A study of Mus musculus with 4 samples.

How the data were processed

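Gene expression was measured with the Visium spatial assay on 4 sections of liver from healthy wild-type mice, numbered 1 to 4 as the titles of the samples give them. For each section the files held a table of UMI counts per gene and spot for the spots over tissue, the same table for all 4992 barcodes of the capture area, and the array position of each barcode. The values used are counts of UMIs that the authors deposited without normalization, made with Space Ranger 1.0.0 per the file headers and the submitters' processing notes. The same notes name the mouse genome build mm10, and Cell Ranger with no version. The gene annotation behind the counts and the way tissue was outlined are not given in the sources used here. Positions of genes came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, matched by Ensembl identifier for 30934 of the 31053 genes in the files. Of these genes 71 shared a symbol with another and were kept apart by identifier. Tissue images and data from other parts of the study were not used here.

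Of 6654 spots over tissue, the 6649 with at least 500 UMIs were kept, which were 1323, 1126, 2481 and 1719 in sections 1 to 4. Counts of each spot were scaled to 10000 and log1p transformed, and landmark genes were z-scored over the spots of a section. The position score of a spot was the mean z-score of the portal landmarks (Cyp2f2, Hal, Sds, Gls2, Hsd17b13, Hsd17b6, Etnppl, Ctsc) minus that of the central landmarks (Cyp2e1, Cyp1a2, Oat, Glul, Slc1a2, Gulo, Lect2, Rgn). Each section was divided by rank of the score into 3 zones of equal size, periportal, middle and pericentral. Inside the periportal zone, the 20% of spots with the highest mean of the tract landmarks (Krt7, Krt19, Krt8, Epcam, Spp1, Sox9, Cldn7, Tm4sf4, Anxa4, Tspan8) were called tract-rich and compared with the other 80%. As a check, portal and central landmark means correlated across spots with a Pearson r of −0.883 to −0.843, the score correlated with log UMIs at 0.0274 to 0.164, and with the mean of the neighbouring spots at 0.822 to 0.855. Spots of 1 section are not independent, so these values carry no p.

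Raw UMI counts were summed per section and region, giving 12 sums for the zones and 8 for the tract comparison, because sections and not spots are the replicates. Region sums were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) with TMM normalization, the filterByExpr filter at its minimum count of 10, section as a block and a Benjamini-Hochberg false discovery rate of 0.05. Zones were fitted together, so that they share 1 estimate of the spread. A gene counted as highest or lowest in the middle zone if it passed against both outer zones in the same direction. The 26 landmark genes stayed in library sizes and were left out of all tests. Fold changes per section were differences of log2 CPM with a prior count of 2. The SE of a fitted log2 fold change was its size over the square root of the test's F statistic. It carries the moderated spread of the fit and can be smaller than the SE of the 4 section values. The same-numbered sums come from 1 section, which is why section was a block. As a check of this pairing, deviations of the zones from their group means correlated across genes at 0.798 to 0.869 within a section and at most at 0.279 with another section. No sections were duplicates, since a chi-square per degree of freedom between their counts was 81.1 to 175.

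Altogether 41 gene lists were fixed before the data were examined, as were the comparisons, tests, landmarks, alternatives and the rule for named genes. Lists with at least 4 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01) on log2 CPM with the same design, beside camera with an estimated correlation and fry. List counts for the middle zone came from the contrast with the mean of both outer zones. Of the list symbols, 4 were not matched to the files and not analysed here (Ccl19, Ccl21a, C5 and Aldoa). Named genes were, per comparison, the 10 with the largest log2 fold change in each direction (5 for the middle zone) among those past the threshold, moving the same way in all 4 sections and at 20 CPM or more on average. Landmarks and predicted genes (names starting in Gm or ending in Rik) were excluded there. Marco, Il10, Clec4f, Timd4, Vsig4, Cd5l, C1qa, Cd163, Csf1r and Adgre1 were named whatever their result, and up to 4 members with the smallest p in each list described. Some members are not reported here. In the middle zone 3 genes met the rule on the low side.

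Marco UMIs per 100 UMIs of the other 17 Kupffer cell genes were compared between zones with an exact two-sided sign-flip permutation test over the 4 sections. Shares of spots with a UMI were taken after thinning each spot to 5000 UMIs without replacement, with shallower spots left out, and set beside the share in spots outside tissue. Median UMIs per spot by section and zone ran from 36064 to 63754 in periportal, 26118 to 53741 in middle and 27117 to 59017 in pericentral zones, and 16.0%, 2.93%, 7.61% and 0.524% of the spots of sections 1 to 4 had under 10000 UMIs. The middle zone had the lowest median in sections 1, 2 and 4, which the linear correlation of score and log UMIs does not show. In section 1 the medians were 49363 in the periportal, 26118 in the middle and 45731 in the pericentral zone.

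The fits were tested on simulated counts drawn from the real means and library sizes, with 50 genes changed by each of 4 folds. For periportal against pericentral zones (12170 genes), 58%, 78%, 96% and 100% of the genes changed 1.25-, 1.5-, 2- and 4-fold were recovered, with 6 false calls among 11956 unchanged genes. For the tract comparison (10954 genes) recovery was 36%, 72%, 84% and 98%, with 8 false calls among 10743, and for middle against pericentral zones (12169 genes) it was 54%, 82%, 96% and 100%, with 7 false calls among 11956. Of the unchanged lists, camera called 0 of 39, 0 of 38 and 0 of 39 at the adjusted threshold. Genes were drawn independently of each other here. In the data the Kupffer cell list had an estimated correlation of 0.485 in the fit of the zones. These counts thus give no false-call rate for lists whose genes vary together.

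Alternatives changed 1 choice at a time. They were DESeq2 1.42.0 with section in the model, median-ratio size factors, no low-count filter, no section block, each section left out, no UMI minimum, only spots with 6 neighbours in tissue, and each spot thinned to 5000 UMIs. For the position score they were the log2 ratio of Cyp2f2 to Cyp2e1 alone, landmarks without this pair, and the first principal component of the 1000 most variable genes detected in at least 5% of spots. For the regions they were outer zones of 20% of spots, 2 zones in place of 3, 10% of spots as tract-rich, and the 40% with the lowest tract score as comparison. For the Marco ratio the sum of Clec4f, Vsig4, Timd4 and Cd5l was another denominator, and shares were also taken at 2000 UMIs and unthinned. A minimum of 10000 UMIs per spot, and the Marco ratio in thinned spots, were added after seeing the data. Scripts ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.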

Results

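Spatial gene expression was measured on 4 sections of healthy wild-type mouse liver with the Visium assay, in which a tissue section lies on an array of barcoded spots. Each spot captures RNA from several cells, and unique molecular identifiers (UMIs) count the captured molecules. All 4 sections belonged to 1 group, so every comparison was made between positions in the liver lobule within a section. The lobule runs from the portal tract, where blood from the gut and the bile ducts lie, to the central vein. The series title concerns macrophages near the portal tract, and the comparisons ask which genes differ along the lobule and which belong to the tract itself. Section 1 held 1325 spots over tissue with 53496213 UMIs, section 2 held 1126 spots with 60729912 UMIs, section 3 held 2484 spots with 75155608 UMIs, and section 4 held 1719 spots with 78415471 UMIs. The median spot of sections 1 to 4 had 43808, 58947, 30848 and 46497 UMIs and 5079, 5485, 4075 and 4865 genes. The labels do not say whether the sections came from separate animals, so the spread between these 4 sections may be technical. Gene p-values from edgeR rest on that spread after moderation over all genes tested, and can be far smaller than 4 sections alone would allow. Those of camera come from comparing the genes of a list with all others.

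Spots were ordered by a position score made of 8 genes known from the periportal side and 8 genes known from the pericentral side of the lobule, and each section was divided by rank into 3 zones of equal size, periportal, middle and pericentral. These landmark genes follow the zones by construction. Of them, Cyp2f2 averaged 1412 ± 204 counts per 1000000 UMIs (CPM; SD, n = 4) in the periportal zone, 1000 ± 109 in the middle zone and 348 ± 51.2 in the pericentral zone. Cyp2e1, a landmark of the other side, averaged 776 ± 61.5, 2602 ± 88.8 and 6285 ± 320 CPM. The zones held 2216, 2216 and 2217 spots over all sections. Inside the periportal zone, the 20% of spots with the highest expression of bile duct landmarks, 443 spots, were called tract-rich, and there Spp1, a landmark, averaged 364 ± 126 CPM against 23.9 ± 11.8 in the 1773 other periportal spots. Landmark genes took no part in any test. RNA also reached spots outside tissue, which held 17.7%, 11.6%, 6.70% and 9.65% of the UMIs of sections 1 to 4, and spots 1 pitch from the tissue edge had 10.9% to 23.8% of the tissue median.

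**Figure D1:**
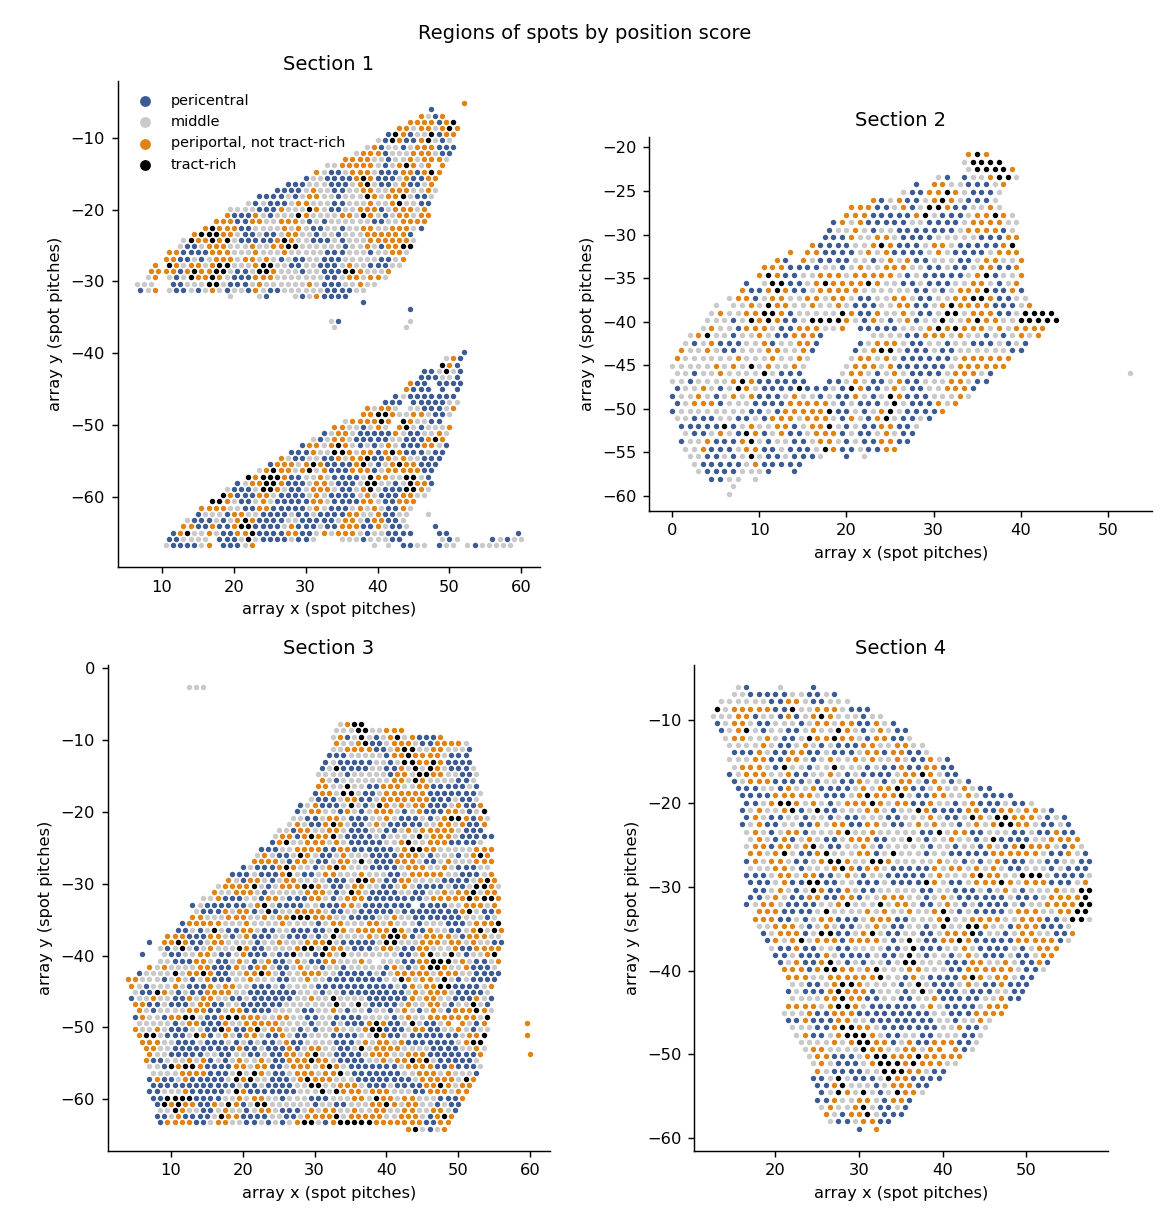
Position of every spot kept in the 4 sections, with array x and y in spot pitches, coloured by region: pericentral zone, middle zone, periportal zone without tract-rich spots, and tract-rich spots. Each region recurs many times across a section, and the 443 tract-rich spots lie scattered among the 1773 other periportal spots.

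The ends of the lobule differed in a large part of the genes tested, and those named first had the largest differences among genes at 20 CPM or more on average over both zones, apart from landmarks and predicted genes. Aldh1b1 (ENSMUSG00000035561, chromosome 4, 45799022 to 45804604 in mouse build mm10), which encodes a mitochondrial aldehyde dehydrogenase, was higher in the periportal than in the pericentral zone by a log2 fold change of 3.19 ± 0.06 (SE), at 58.9 ± 17.3 against 6.82 ± 1.41 CPM (SD, n = 4). Cib3 (2.77 ± 0.13), Cryl1 (2.55 ± 0.06), Serpina12, which encodes vaspin (2.31 ± 0.14), and Tstd1 (2.28 ± 0.12) followed. The level of Cib3 over all tissue spots was 104 CPM in section 3, against 19.5, 6.72 and 17.3 CPM in sections 1, 2 and 4. On the pericentral side stood Cyp2c38 (ENSMUSG00000032808, chromosome 19, 39389556 to 39463075; −3.74 ± 0.06), Lhpp, which encodes a phosphohistidine phosphatase (ENSMUSG00000030946, chromosome 7, 132610638 to 132706420; −3.64 ± 0.05, 7.04 ± 0.535 against 93.6 ± 7.85 CPM), Cyp2c40 (−3.60 ± 0.07) and Serpina7, which encodes thyroxine-binding globulin (−3.44 ± 0.07). Of 12257 genes tested, 2362 were higher and 2358 lower in the periportal zone at a false discovery rate of 0.05, 38.5% in all.

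All genes named here moved the same way in 4 of 4 sections, which the rule for naming them asked for. Their adjusted p ran from 2.77e-42 for Lhpp to 1.37e-05 for Serpina12 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The other genes with the largest differences at that level were Slc3a1, a subunit of a cystine transporter (2.20 ± 0.06), Bdh2 (1.84 ± 0.06), Clec2h (1.82 ± 0.06), Gldc, which breaks down glycine (1.75 ± 0.04), and the transcription factor gene Foxq1 (1.72 ± 0.06) on the periportal side. On the pericentral side they were Cyp2a5 (−3.19 ± 0.05), Cyp2c37 (−3.06 ± 0.07), Mup17 (−3.01 ± 0.10), Fitm1 (−2.90 ± 0.11), Aldh3a2, a fatty aldehyde dehydrogenase (−2.87 ± 0.15), and Cib2 (−2.83 ± 0.13). The call of 4345 of the 4720 genes had the same direction in all 4 sections, and 386 genes were over 2-fold higher and 244 over 2-fold lower. Genes of the Cyp2c and Mup families have near-identical copies, so the split of their UMIs between members is uncertain. The regions were set by landmark genes counted in the same spots, and with each spot thinned to 5000 UMIs the count was 1600 genes of 8548 tested. Without the section as a block it was 1208.

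Kupffer cell genes, those of the resident macrophages of the liver sinusoids, were higher near the portal tract. Marco (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024, minus strand), which encodes a scavenger receptor that binds bacteria, had the largest difference of the list, a log2 fold change of 1.45 ± 0.11, and averaged 7.38 ± 4.09 CPM in the periportal zone, 5.24 ± 2.59 in the middle zone and 2.90 ± 1.39 in the pericentral zone (SD, n = 4). Clec4f, a lectin gene of Kupffer cells (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187), was at 57.2 ± 5.35 against 34.6 ± 4.76 CPM (log2 0.82 ± 0.05). Csf1r, the receptor for macrophage colony-stimulating factor (0.90 ± 0.05), Cd5l (0.88 ± 0.09), Timd4, a receptor for dying cells (0.81 ± 0.12), Adgre1 (0.80 ± 0.07), the complement genes C1qa (0.78 ± 0.08) and C1qb (0.73 ± 0.04), Vsig4, a complement receptor gene (0.74 ± 0.05), and Cd163, the haemoglobin scavenger receptor gene (0.73 ± 0.12), were higher too.

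Of the 18 Kupffer cell genes tested, 17 were higher in the periportal zone, 0 were lower and 1 did not pass, and the counts were the same adjusted over the list alone. The list's median log2 fold change was 0.74 and camera gave an adjusted p = 1.68e-12, with adjusted p = 0.11 with an estimated correlation. Marco had an adjusted p of 8.38e-15 in edgeR's quasi-likelihood test, was higher in 4 of 4 sections, with log2 fold changes of 1.56, 0.87, 1.51 and 1.63 in sections 1 to 4, and ranked first of the 18 genes in each of them. Without the section as a block, its adjusted p was 9.75e-02 at a log2 fold change of 1.44. Thinning ended the call of Timd4 (0.54), and dividing each section into 2 zones ended that of Cd163 (0.58). The share of UMIs from mitochondrially encoded genes averaged 10.5% ± 1.29 in the periportal zone and 9.34% ± 0.840 in the pericentral zone (SD, n = 4).

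**Figure D2:**
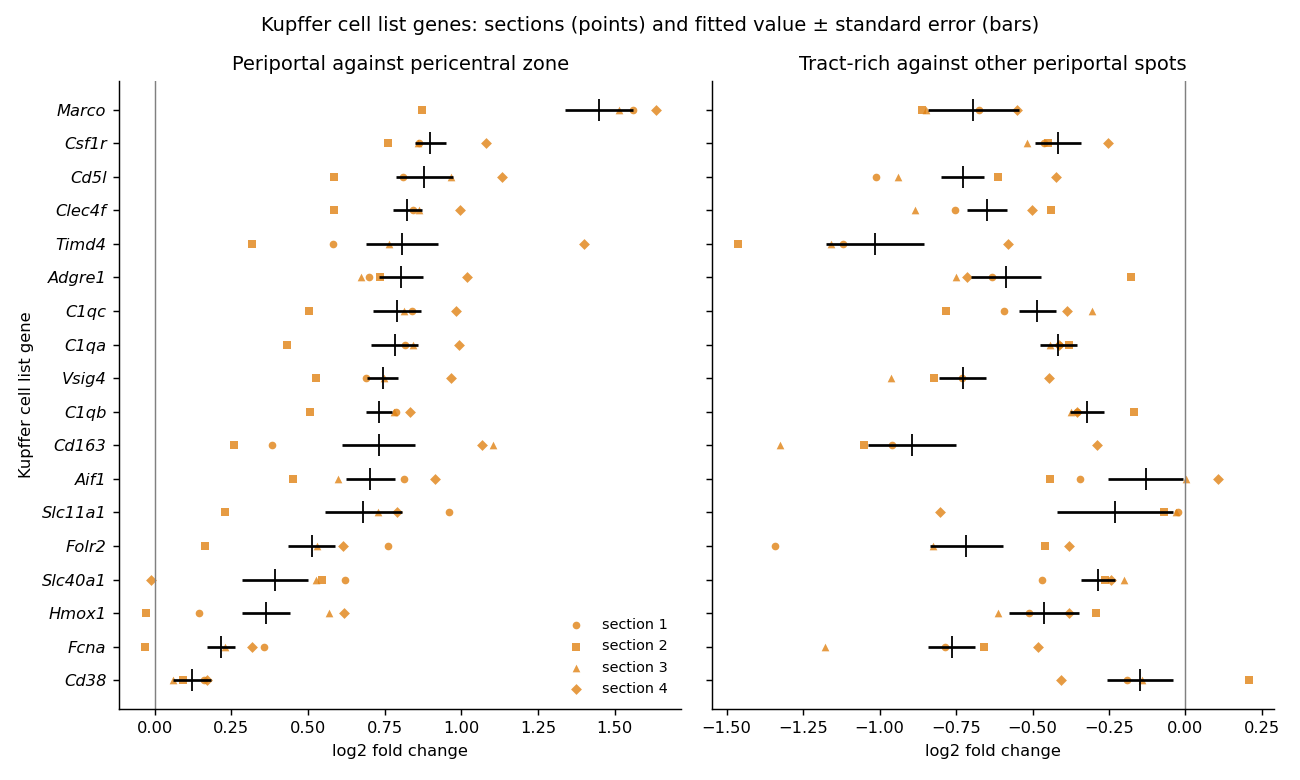
Log2 fold changes of the 18 Kupffer cell list genes between the periportal and pericentral zones (left) and between tract-rich and other periportal spots (right); points are the 4 sections and black marks the fitted value with bars of ± 1 SE. Marco lies farthest to the right on the left side at 1.45, and at −0.69 on the right side, where 15 of the 18 genes were lower.

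Relative to the other Kupffer cell genes, Marco was higher near the portal tract as well. Per 100 UMIs of the other 17 genes of the list there were 1.27 ± 0.630 Marco UMIs in the periportal zone and 0.739 ± 0.332 in the pericentral zone (SD, n = 4). The log2 ratio of these values averaged 0.78 ± 0.23 (SD) and was above 0 in 4 of 4 sections, with p = 0.13 in an exact two-sided sign-flip permutation test, the smallest p that 4 sections allow. It was 0.61 with the sum of Clec4f, Vsig4, Timd4 and Cd5l as denominator, 0.62 with 2 zones in place of 3, 1.15 with outer zones of 20% of spots and 1.20 ± 0.87 (SD) after thinning, a setting chosen after seeing the data.

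After each spot was thinned to 5000 UMIs, Marco was detected in 3.47% ± 2.51 of periportal and 1.70% ± 1.19 of pericentral spots (SD, n = 4). Its share in the 1480 spots outside tissue with at least that depth averaged 2.06% over the sections. Clec4f was detected in 24.3% ± 0.668 against 16.6% ± 2.25 of spots, with 18.2% outside tissue, and Cd5l in 26.1% ± 1.09 against 17.7% ± 1.72, with 19.4% outside. Timd4 was detected in 3.39% ± 0.528 against 2.05% ± 1.02 of spots, both below the mean of 3.83% outside tissue. Both zones lay below the outside share in sections 2 to 4 and above it in section 1. The profile outside tissue followed that of the tissue (Pearson r of 0.979 to 0.996 across genes at 20 CPM or more). At equal depth the share outside is therefore no background level. At this depth each of the 4 genes was detected more often in the periportal than in the pericentral zone in 4 of 4 sections, with p = 0.13 in the exact sign-flip permutation test, the smallest possible. At 2000 UMIs that held for Clec4f and Cd5l, but Marco was detected more often there in 3 of 4 sections (p = 0.25 in that permutation test) and Timd4 in 2 of 4 (p = 0.75). In the middle zone, at 5000 UMIs, Marco was detected in 4.99%, 2.68%, 1.87% and 3.32% of spots in sections 1 to 4, against 2.72%, 2.40%, 1.59% and 7.17% in the periportal zone. The middle share was above the periportal one in sections 1 and 2 for Clec4f, 2 to 4 for Timd4, and 1 and 3 for Cd5l. Unthinned, the shares were 25.0% ± 12.8 against 11.7% ± 6.80 for Marco, 83.0% ± 7.43 against 66.0% ± 11.6 for Clec4f, 26.0% ± 5.67 against 16.5% ± 6.47 for Timd4 and 83.9% ± 6.22 against 66.8% ± 10.4 for Cd5l. Over all 13314 spots outside tissue, most of them shallow, they averaged 1.38%, 9.06%, 1.37% and 8.04% over the sections, in that order. Il10, the gene of an anti-inflammatory cytokine, had 14 UMIs in all sections, of which 8 lay in the periportal, 4 in the middle and 2 in the pericentral zone, too few to test. Its unthinned share was 0.463% ± 0.579 of periportal and 0.0968% ± 0.126 of pericentral spots, and thinned it was 0 of 6561 spots, which sets no limit for a gene with so few UMIs.

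Among other immune genes, those of antigen presentation and several chemokines were higher in the periportal zone. Of the 8 genes tested of dendritic cells and MHC class II, 6 were higher and 2 did not pass, with Cd74 at 0.83 ± 0.04 and H2-Ab1 at 0.79 ± 0.05 (camera adjusted p = 2.14e-05, and adjusted p = 0.11 with an estimated correlation). MHC class I had 5 of 11 genes higher, 0 lower and 6 not past, all by small amounts, such as B2m at 0.27 ± 0.03 and H2-D1 at 0.25 ± 0.03 (adjusted p = 6.32e-03, and adjusted p = 0.28 with an estimated correlation). In the chemokine list 8 of 13 genes were higher, 2 lower and 3 not past. Ccl9 stood at 1.0 ± 0.03, Cxcl16 at 0.51 ± 0.07 and Ccl25 at −0.74 ± 0.09 (adjusted p = 6.90e-03, and adjusted p = 0.087 with an estimated correlation). Of 16 immune-regulating genes, 9 were higher, 2 lower and 5 not past. Il1rn, the antagonist of the interleukin 1 receptor, stood at 1.54 ± 0.21, Il18bp, which binds interleukin 18, at 0.81 ± 0.06, and Pros1 at −0.32 ± 0.05 (adjusted p = 1.68e-02, and adjusted p = 0.11 with an estimated correlation). Genes of monocytes and capsular macrophages were higher in 9 of 11 cases, lower in 1 and not past in 1, with Cd14 at 1.26 ± 0.15, Lgals3 at 0.77 ± 0.09 and Fabp5 at −0.51 ± 0.06 (adjusted p = 7.91e-03, and adjusted p = 0.16 with an estimated correlation). Thinning ended the list calls of the immune-regulating genes (median 0.22) and of the monocytes and capsular macrophages (0.36).

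Acute phase proteins, which hepatocytes secrete, had 14 of 18 genes higher, 0 lower and 4 not past, led by Hpx, which binds haem (1.0 ± 0.03), Itih3 (0.70 ± 0.03) and Orm1 (0.66 ± 0.03), with an adjusted p = 7.27e-09 and adjusted p = 0.15 with an estimated correlation. The complement list had 12 of 20 genes higher, 5 lower and 3 not past. C8a stood at 0.64 ± 0.03 and Cfi at 0.49 ± 0.03 (adjusted p = 5.43e-04, and adjusted p = 0.32 with an estimated correlation). Pigr, the receptor that carries immunoglobulin A into bile, was higher by 1.33 ± 0.03, in a list of antimicrobial proteins and IgA transport with 4 of 11 genes higher, 2 lower and 5 not past (adjusted p = 8.98e-02). Genes that sense microbial products had 6 of 13 higher, 3 lower and 4 not past. Pglyrp2 stood at 0.68 ± 0.04 and Tlr5, a flagellin receptor gene of low level, at −2.54 ± 0.46 (adjusted p = 2.06e-01). Interferon-stimulated genes had 4 of 17 higher, 3 lower and 10 not past. Irf7 stood at 1.0 ± 0.05 and Ifi27l2b at −0.45 ± 0.11 (adjusted p = 2.95e-01). Lists of circulating white cells rested on few UMIs. The neutrophil list had 1 of 6 genes higher, Il1b, which encodes interleukin 1 beta (1.32 ± 0.12), with 0 lower and 5 not past (adjusted p = 1.69e-01). B and plasma cells had 2 of 9 genes higher, Iglc2 (1.02 ± 0.33) and Mzb1 (1.09 ± 0.38), with 0 lower and 7 not past (adjusted p = 7.70e-01), and T and NK cells had 2 of 7 higher, Trbc2 (0.60 ± 0.19) and Cd3d (0.64 ± 0.24), with 0 lower and 5 not past (adjusted p = 4.66e-01). DESeq2 did not call Iglc2 (1.10), Mzb1 (1.07), Trbc2 (0.59) or Cd3d (0.70), and thinning ended the calls of Il1b (0.91), Ccl25 (−0.58), Pros1 (−0.09) and Ifi27l2b (−0.25).

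Endothelial genes differed in opposite directions at the ends of the lobule. Of 14 periportal endothelium genes, 11 were higher in the periportal zone, 2 lower and 1 not past, and 12 were higher adjusted over the list alone. Ntn4, a netrin gene, stood at 1.89 ± 0.11, Msr1 at 1.4 ± 0.10 and the Notch ligand gene Dll4 at 1.23 ± 0.13 (camera adjusted p = 1.08e-04, and adjusted p = 0.041 with an estimated correlation). Of 13 pericentral endothelium genes, 0 were higher, 9 lower and 4 not past. These included Rspo3 (−2.28 ± 0.13) and Wnt2 (−1.80 ± 0.12), which encode activators of Wnt signalling, and Kit (−2.0 ± 0.15), with an adjusted p = 7.25e-06 and adjusted p = 0.024 with an estimated correlation. Genes of sinusoidal endothelium at any position went both ways, with 5 of 16 higher, 3 lower and 8 not past, such as Gpr182 at 0.33 ± 0.05 and Stab1 at −0.26 ± 0.05 (adjusted p = 6.02e-01). Stellate cells, the pericytes of the sinusoid, had 6 of 15 genes higher, 4 lower and 5 not past. Reln stood at −0.56 ± 0.04 (adjusted p = 9.72e-01). Bile duct genes that were not landmarks had 10 of 11 higher, 0 lower and 1 not past. Cdh1, which encodes E-cadherin and is also made by hepatocytes, stood at 2.47 ± 0.07, Cd24a at 2.04 ± 0.18 and Bicc1 at 1.90 ± 0.21 (adjusted p = 4.20e-07, and adjusted p = 0.053 with an estimated correlation). Portal fibroblasts and matrix had 8 of 15 genes higher, 1 lower and 6 not past. Cd34 stood at 1.98 ± 0.29 and Dpt at 0.96 ± 0.16 (adjusted p = 5.47e-03, and adjusted p = 0.16 with an estimated correlation). Smooth muscle had 4 of 6 higher, 1 lower and 1 not past. Tagln stood at 0.89 ± 0.11 and the tropomyosin gene Tpm2 at −1.89 ± 0.09 (adjusted p = 2.26e-01). Blood cells had 1 of 6 higher, Pf4 (0.45 ± 0.14, not called by DESeq2), 0 lower and 5 not past, with a list median of −0.32 (adjusted p = 6.52e-01), and of mesothelium and capsule only 2 genes were tested, neither past the test. Thinning ended the list calls of periportal endothelium (median 0.73) and of portal fibroblasts and matrix (0.26), and the gene calls of Gpr182 (0.20) and Stab1 (−0.20).

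Metabolic genes split between the ends of the lobule by pathway. Of 10 gluconeogenesis genes, 8 were higher in the periportal zone, 1 lower and 1 not past. The fructose bisphosphatase gene Fbp1 stood at 0.80 ± 0.03 and its regulator Ppargc1a at 1.26 ± 0.14 (camera adjusted p = 8.96e-07, and adjusted p = 0.022 with an estimated correlation). Amino acid breakdown had 11 of 18 genes higher, 6 lower and 1 not past. Sdsl stood at 2.23 ± 0.08, Ftcd of histidine breakdown at 0.93 ± 0.03 and the proline oxidase gene Prodh at −1.23 ± 0.03 (adjusted p = 1.58e-03, and adjusted p = 0.053 with an estimated correlation). In the urea cycle and ammonia list, 6 of 10 genes were higher and 4 lower. The cycle enzymes Arg1 (0.76 ± 0.03), Asl (0.73 ± 0.03) and Ass1 (0.68 ± 0.03) were higher and the ammonia transporter gene Rhbg was lower (−2.94 ± 0.12), so the list's median was 0.28, its mean −0.05 and its camera direction upward (adjusted p = 7.42e-02). Glycolysis and glucose uptake had 7 of 10 higher, 1 lower and 2 not past. Gapdh stood at 0.49 ± 0.03 and Khk at 0.42 ± 0.03 (adjusted p = 1.08e-03, and adjusted p = 0.092 with an estimated correlation). Plasma proteins and apolipoproteins had 13 of 18 higher, 4 lower and 1 not past. Apoa4 stood at 1.25 ± 0.05 and Apoc3 at 0.51 ± 0.02 (adjusted p = 1.90e-06, and adjusted p = 0.16 with an estimated correlation). Notch, Hedgehog and Ras-side regulators had 10 of 14 higher, 2 lower and 2 not past. Igf1 stood at 0.68 ± 0.03 and Dusp6 at −0.59 ± 0.07 (adjusted p = 1.06e-03, and adjusted p = 0.090 with an estimated correlation). Thinning ended the call of Dusp6 (−0.44).

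On the pericentral side stood detoxification, bile acid synthesis and the oxidation of fatty acids. Of 18 cytochrome P450 drug metabolism genes, 2 were higher in the periportal zone, 14 lower and 2 not past. Cyp2c29 stood at −2.76 ± 0.03 and the receptor genes Ahr at −2.09 ± 0.06 and Nr1i3, which encodes the constitutive androstane receptor, at −1.91 ± 0.04 (camera adjusted p = 3.60e-12, and adjusted p = 0.015 with an estimated correlation). Glutathione and phase II enzymes had 5 of 20 higher, 13 lower and 2 not past. Gsta3 stood at −1.18 ± 0.03 and Gstm1 at −0.69 ± 0.03 (adjusted p = 3.21e-05, and adjusted p = 0.092 with an estimated correlation). Bile acid synthesis and transport had 1 of 18 higher, 12 lower and 5 not past. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at −2.82 ± 0.10, Cyp8b1 at −1.14 ± 0.04 and the transporter gene Slco1b2 at −1.81 ± 0.03 (adjusted p = 6.84e-08, and adjusted p = 0.073 with an estimated correlation). Fatty acid oxidation and ketogenesis had 1 of 14 higher, 12 lower and 1 not past. Ehhadh stood at −0.69 ± 0.03 (adjusted p = 5.41e-09, and adjusted p = 0.038 with an estimated correlation). Wnt targets and pericentral regulators had 0 of 16 higher, 14 lower and 2 not past. Notum, which encodes a Wnt inhibitor, stood at −1.73 ± 0.06 (adjusted p = 7.49e-15, and adjusted p = 7.71e-03 with an estimated correlation).

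Several lists had members on both sides and no call. Fatty acid synthesis had 5 of 12 genes higher, 3 lower and 4 not past. The citrate lyase gene Acly stood at 1.08 ± 0.04 and the malic enzyme gene Me1 at −0.80 ± 0.04 (camera adjusted p = 3.47e-01). Cholesterol synthesis had 5 of 16 higher, 5 lower and 6 not past (adjusted p = 1.41e-01). Major urinary proteins, pheromone carriers made in bulk by the mouse liver, had 4 of 10 higher, 3 lower and 3 not past. Mup20 stood at 1.32 ± 0.04 against the −3.01 of Mup17 (adjusted p = 9.67e-01). The circadian clock list had 3 of 14 higher, 2 lower and 9 not past. Cry1 stood at 0.86 ± 0.09 and Nr1d1 at −0.22 ± 0.05 (adjusted p = 2.30e-01). Immediate early and stress genes had 7 of 13 higher, 3 lower and 3 not past. Egr1 stood at 1.28 ± 0.17, Gadd45g at 0.73 ± 0.04 and the heat shock gene Hspa1b at −1.37 ± 0.08 (adjusted p = 9.71e-02). The cell cycle list had 2 of 15 higher, 2 lower and 11 not past, among them Ccne1 (0.53 ± 0.18) and Mcm2 (−0.57 ± 0.17), neither called by DESeq2 (adjusted p = 7.70e-01). By contrast, mitochondrially encoded genes passed camera, with 11 of 13 higher, 0 lower and 2 not past, such as mt-Cytb at 0.38 ± 0.03 (adjusted p = 3.52e-07, and adjusted p = 0.20 with an estimated correlation). Adjusted over the list alone, counts higher and lower were 13 and 5 for complement, 6 and 4 for sinusoidal endothelium, 7 and 4 for stellate cells, 5 and 1 for smooth muscle, 7 and 3 for fatty acid synthesis, 5 and 6 for cholesterol synthesis, and 3 and 14 for cytochrome P450. They were 1 and 14 for Wnt targets, 11 and 2 for Notch, Hedgehog and Ras-side regulators, 14 and 4 for plasma proteins, 13 and 0 for mitochondrially encoded genes, 8 and 4 for immediate early and stress genes, and 1 and 2 for the cell cycle. Apart from these and periportal endothelium, no count changed when adjusted over the list alone. In all, 23 of 40 lists passed camera, 17 upward and 6 downward, and 6 with an estimated correlation, those of both zone-specific endothelium lists, gluconeogenesis, fatty acid oxidation, cytochrome P450 and Wnt targets.

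**Figure D3:**
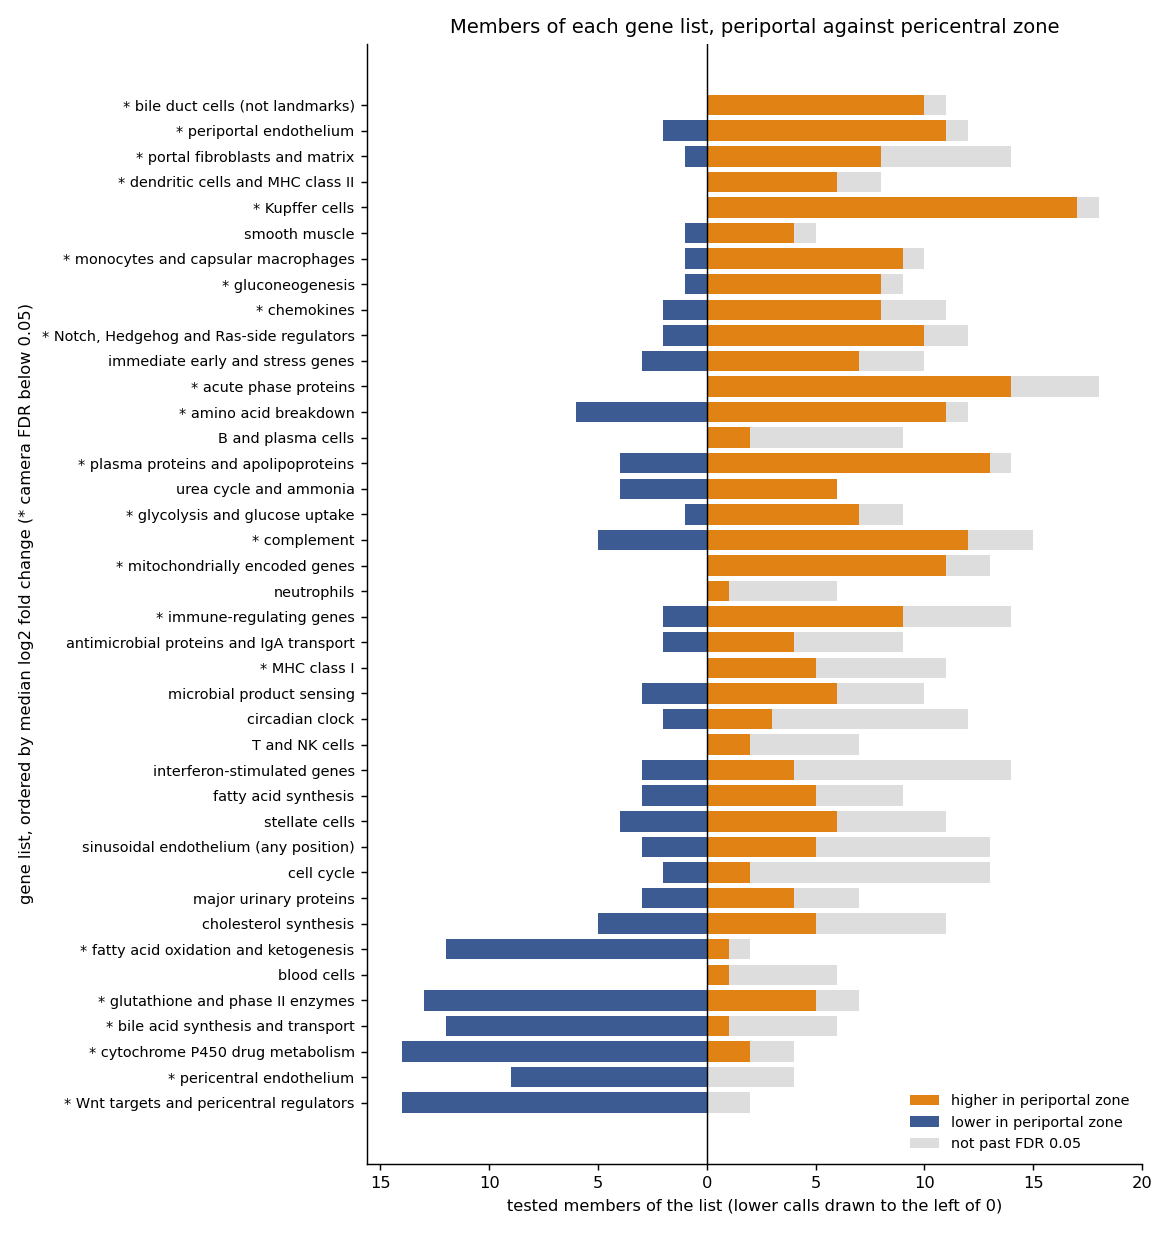
Number of tested genes of each list that were higher (right of 0), lower (left of 0) or not past the test (grey) between the periportal and pericentral zones, with lists ordered by median log2 fold change and those past camera marked by a star. Kupffer cells have 17 of 18 genes to the right, and Wnt targets and pericentral regulators have 14 of 16 to the left.

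In the middle of the lobule, the gene of hepcidin, the hormone that limits iron uptake, was expressed more than at either end. Hamp (ENSMUSG00000050440, chromosome 7, 30942368 to 30944032) averaged 1701 ± 925 CPM in the middle zone, 1189 ± 858 in the periportal zone and 1190 ± 796 in the pericentral zone (SD, n = 4), with log2 fold changes of 0.60 ± 0.09 and 0.66 ± 0.09 (SE) against them. Igfbp2, which encodes a carrier of insulin-like growth factors, was at 678 ± 151 CPM (0.35 ± 0.07 and 0.64 ± 0.07), the carboxylesterase gene Ces1e at 95.5 ± 19.2 CPM (0.22 ± 0.03 and 0.26 ± 0.03), and Ces1b (0.29 ± 0.04 and 0.14 ± 0.04) and Fcgr2b, an Fc receptor gene of sinusoidal endothelium (0.14 ± 0.04 and 0.24 ± 0.04), were also highest there. Fabp4, a fatty acid carrier gene, was lowest in the middle zone (−0.28 ± 0.06 and −1.09 ± 0.05), as were Sucnr1 (−0.13 ± 0.04 and −0.12 ± 0.04) and Nudt7 (−0.08 ± 0.03 and −0.13 ± 0.03). In 4 of 4 sections each of these moved the same way against both zones, which the rule for naming them asked for.

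The test asked for a difference from both outer zones, each at a false discovery rate of 0.05, and 20 genes were highest and 14 lowest in the middle, 34 of 12257, against 1627 genes that differed between middle and periportal zones and 2712 between middle and pericentral zones. The adjusted p of Hamp was 5.31e-03 against the periportal and 1.80e-03 against the pericentral zone in edgeR's quasi-likelihood test, and that of Ces1e 5.50e-07 and 1.42e-08. Against the mean of the outer zones, 18 of 40 lists passed camera, 16 upward and 2 downward, and 0 with an estimated correlation, where 10 had an unadjusted p under 0.05 (fry called 8). Of the 18 Kupffer cell genes, 8 were higher than that mean, 0 lower and 10 not past, and 15 were higher adjusted over the list alone (median 0.25, camera adjusted p = 4.19e-23, and adjusted p = 0.071 with an estimated correlation). Against the periportal zone alone, 3 of the 18 were lower in the middle, Marco (−0.54 ± 0.10), Adgre1 (−0.20 ± 0.07) and C1qb (−0.14 ± 0.04), and the others did not pass, such as Clec4f at 53.6 ± 5.58 against 57.2 ± 5.35 CPM. Urea cycle and ammonia genes were again set against the mean of both outer zones, a contrast that does not ask for a peak. They had 6 of 10 higher, 1 lower and 3 not past, with 7 and 1 adjusted over the list alone (median 0.12, camera adjusted p = 9.49e-10, and adjusted p = 0.056 with an estimated correlation). Of the 5 genes named as highest in the middle, Ces1e alone kept its call with each section left out and in each other setting that kept the section block. DESeq2 called 8 genes in place of 34, edgeR without the section block 0 (10 at an unadjusted p under 0.05), thinned spots gave 6, and leaving out sections 1, 2 or 4 gave 16, 21 or 12. The middle zone had the fewest UMIs per spot by median in sections 1, 2 and 4. With at least 10000 UMIs per spot, a setting chosen after seeing the data, the count was 30.

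**Figure D4:**
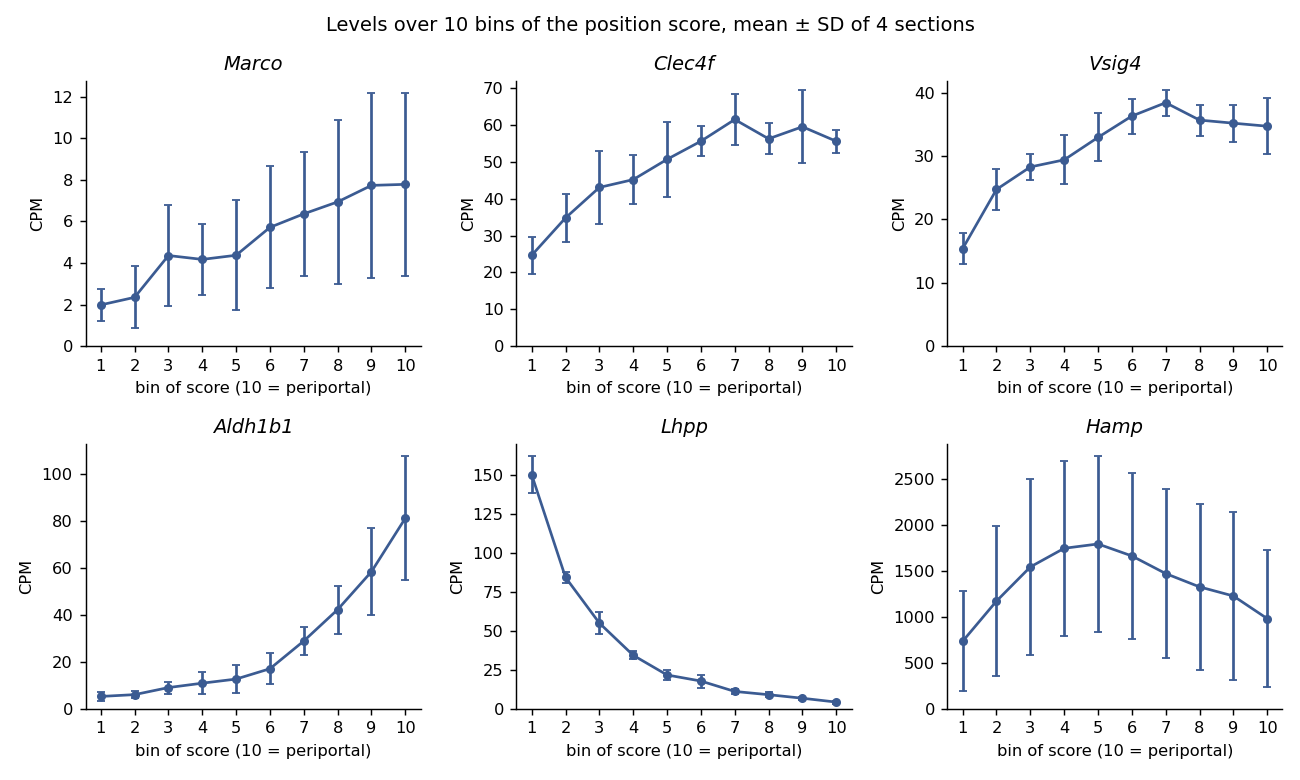
Mean level in CPM (bars, ± SD of the 4 sections) of 6 genes over 10 bins of the position score, from the most pericentral (1) to the most periportal (10). Marco and Aldh1b1 climb towards the periportal end, Clec4f and Vsig4 level off from the middle, Lhpp falls from the pericentral end, and Hamp peaks in the middle.

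Within the periportal zone, spots rich in bile duct RNA were also rich in genes of connective tissue. Mgp, matrix Gla protein, an inhibitor of calcification (ENSMUSG00000030218, chromosome 6, 136872435 to 136875823), was at 37.4 ± 10.3 CPM in tract-rich and 3.11 ± 1.47 in other periportal spots (SD, n = 4), a log2 fold change of 3.49 ± 0.11 (SE). Gsn, the actin-severing gelsolin (2.92 ± 0.07), Gas6, the ligand of the TAM receptors (2.52 ± 0.08), Mfge8 (1.79 ± 0.08), Tmsb10 (1.70 ± 0.06), Col3a1, a collagen gene (1.53 ± 0.09), Ly6a (1.51 ± 0.11), Crip1 (1.46 ± 0.08), H2-Eb1 (1.4 ± 0.21) and Tagln2 (1.27 ± 0.08) were higher. Among genes at 20 CPM or more on average over both classes of spots, those with the largest drops were Cyp2c54 (−0.87 ± 0.06), the ficolin gene Fcna (−0.76 ± 0.08), Hsd3b5 (−0.76 ± 0.14), Cyp2c50 (−0.74 ± 0.05), Cd5l (−0.73 ± 0.07), Vsig4 (−0.73 ± 0.08), Reln (−0.70 ± 0.09), Sult2a8 (−0.67 ± 0.11), Clec4f (−0.65 ± 0.06) and Rnase4 (−0.64 ± 0.06). Of 11196 genes tested, 799 were higher and 771 lower, and 357 were over 2-fold higher but 6 over 2-fold lower. Over 10 bins of the position score, Col3a1 and Gas6 were at 20.9 ± 9.1 and 22.7 ± 4.0 CPM in the most pericentral bin. In the most periportal bin they were at 17.2 ± 6.9 and 19.6 ± 7.0 CPM, while the other genes named as higher were above their pericentral values there. A comparison within the periportal zone thus does not assign Col3a1 or Gas6 to the portal tract alone.

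Kupffer cell genes were thus lower in tract-rich spots, although higher in the periportal zone that contains these spots. Marco was at 5.14 ± 3.27 CPM in tract-rich and 7.91 ± 4.29 in other periportal spots (−0.69 ± 0.15), Timd4 stood at −1.01 ± 0.16, Cd163 at −0.89 ± 0.14, Adgre1 at −0.59 ± 0.11, and C1qa and Csf1r at −0.42, with SE of 0.06 and 0.07. Of the 18 genes 0 were higher, 15 lower and 3 not past, as when adjusted over the list alone (median −0.54, camera adjusted p = 2.88e-19, and adjusted p = 0.15 with an estimated correlation). Marco's adjusted p was 2.56e-04 in edgeR's quasi-likelihood test, and each Kupffer cell gene named in this paragraph was lower in 4 of 4 sections. Thinning ended the calls of C1qa (−0.45), Cd163 (−0.69), Csf1r (−0.65) and Adgre1 (−0.90), with 189 genes called in all.

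Lists of the tract's tissues were higher in tract-rich spots. Portal fibroblasts and matrix had 11 of 13 genes higher, 0 lower and 2 not past. Dpt stood at 2.97 ± 0.19 and Mfap4 at 3.32 ± 0.26, and 13 were higher adjusted over the list alone (camera adjusted p = 1.82e-31, and adjusted p = 0.048 with an estimated correlation). Bile duct genes that were not landmarks had 10 of 11 higher, 0 lower and 1 not past, also adjusted over the list alone. Tract-rich spots were chosen by other bile duct genes in the same counts, so a rise of this list follows largely from that choice. Cd24a stood at 3.27 ± 0.18, Bicc1 at 3.01 ± 0.21 and Prom1 at 3.51 ± 0.30 (adjusted p = 1.88e-18, and adjusted p = 0.048 with an estimated correlation). All 6 smooth muscle genes tested were higher, with Acta2 at 2.85 ± 0.19, Myh11 at 2.17 ± 0.31 and Tagln at 1.89 ± 0.09 (adjusted p = 4.05e-13, and adjusted p = 0.16 with an estimated correlation). Periportal endothelium had 8 of 14 genes higher, 0 lower and 6 not past. Vwf, the von Willebrand factor gene, stood at 2.67 ± 0.16, Cd34 at 2.77 ± 0.29 and Ltbp4 at 0.56 ± 0.07, and 10 were higher adjusted over the list alone (adjusted p = 2.55e-08, and adjusted p = 0.15 with an estimated correlation). The pericentral endothelium list, which was lower in the periportal zone, was here higher in 5 of 12 genes, lower in 2 and not past in 5, with Fabp4 at 1.14 ± 0.08, Dkk3 at 2.07 ± 0.35 and Bmp2 at −0.38 ± 0.11 (adjusted p = 3.77e-02, and adjusted p = 0.52 with an estimated correlation). Sinusoidal endothelium had 2 of 16 genes higher, 7 lower and 7 not past. Clec4g stood at −0.47 ± 0.06, Mrc1 at −0.44 ± 0.07 and Pecam1 at 0.70 ± 0.10 (adjusted p = 2.40e-02, and adjusted p = 0.52 with an estimated correlation). Of these lists, thinning ended the calls of periportal (median 0.23) and sinusoidal endothelium (−0.22), and leaving out any of sections 1, 2 or 4 ended that of pericentral endothelium.

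Some other immune lists and that of blood cells were higher as well. Dendritic cells and MHC class II had 3 of 7 genes higher, 0 lower and 4 not past, and 6 higher adjusted over the list alone. H2-DMa stood at 0.82 ± 0.15 and H2-DMb1 at 0.80 ± 0.17 (camera adjusted p = 2.15e-11, and adjusted p = 0.16 with an estimated correlation). T and NK cells had 2 of 4 higher, 0 lower and 2 not past, Ccl5 (0.83 ± 0.15) and Nkg7 (1.13 ± 0.31), genes of cytotoxic lymphocytes (adjusted p = 2.81e-02, and adjusted p = 0.52 with an estimated correlation). Monocytes and capsular macrophages had 2 of 9 higher, 0 lower and 7 not past, S100a4 (2.07 ± 0.31) and Plac8 (0.44 ± 0.10), and 4 higher and 1 lower adjusted over the list alone (adjusted p = 2.40e-02, and adjusted p = 0.52 with an estimated correlation). Blood cells had 2 of 6 higher, 0 lower and 4 not past, Pf4 (1.19 ± 0.21) and Hbb-bt (1.07 ± 0.13), and 5 higher adjusted over the list alone (adjusted p = 6.29e-13, and adjusted p = 0.15 with an estimated correlation). The cell cycle list had 1 of 9 higher, Ccnd1 (0.99 ± 0.13), 0 lower and 8 not past (adjusted p = 4.52e-02, and adjusted p = 0.39 with an estimated correlation). The calls of H2-Eb1, Hbb-bt and Nkg7 each ended with some section left out, and those of the list of T and NK cells without section 3, of the monocyte list without sections 1 or 3, and of the cell cycle list without sections 1 or 2. Camera did not call the lists of neutrophils (median −0.34, adjusted p = 4.75e-01), interferon-stimulated genes (−0.007, adjusted p = 8.93e-01), microbial product sensing (0.008, adjusted p = 8.04e-01), MHC class I (0.09, adjusted p = 3.81e-01), chemokines (0.26, adjusted p = 9.39e-01) and immune-regulating genes (−0.07, adjusted p = 8.04e-01). Of these, fry called MHC class I upward and chemokines downward.

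Many hepatocyte lists were lower in tract-rich spots by small amounts, and others were not called. Complement had 0 of 20 genes higher, 10 lower and 10 not past, such as Mbl2 at −0.25 ± 0.05 (camera adjusted p = 6.16e-06, and adjusted p = 0.56 with an estimated correlation). Fatty acid oxidation had 9 of 14 genes lower, Cyp4a14 at −0.56 ± 0.05 among them (adjusted p = 5.08e-09, and adjusted p = 0.31 with an estimated correlation), and bile acid synthesis and transport 12 of 17, with Slco1b2 at −0.51 ± 0.05 (adjusted p = 1.32e-08, and adjusted p = 0.45 with an estimated correlation). Cytochrome P450 had 10 of 18 lower and 1 higher, Cyp1a1, at 2.56 ± 0.20 (adjusted p = 3.05e-09, and adjusted p = 0.34 with an estimated correlation). Major urinary proteins had 4 of 9 lower and 2 higher, with Mup1 at −0.63 ± 0.05 (adjusted p = 5.55e-07, and adjusted p = 0.39 with an estimated correlation). Mitochondrially encoded genes had 9 of 13 lower, with mt-Nd2 at −0.21 ± 0.04 (adjusted p = 7.29e-07, and adjusted p = 0.45 with an estimated correlation), and the urea cycle 5 of 10, with Cps1 at −0.22 ± 0.04 (adjusted p = 2.88e-03, and adjusted p = 0.56 with an estimated correlation). Amino acid breakdown had 5 of 18 lower, with Hgd at −0.17 ± 0.04 (adjusted p = 5.49e-03, and adjusted p = 0.63 with an estimated correlation), glutathione and phase II enzymes 7 of 19, with Gsta3 at −0.26 ± 0.04 (adjusted p = 1.01e-02, and adjusted p = 0.56 with an estimated correlation), and plasma proteins 7 of 18 with 1 higher, with Serpina1a at −0.23 ± 0.04 (adjusted p = 4.13e-03, and adjusted p = 0.63 with an estimated correlation). Adjusted over the list alone, the genes lower numbered 16 for complement, 12 for fatty acid oxidation, 12 for bile acids, 11 for cytochrome P450, 6 for major urinary proteins, 12 for mitochondrially encoded genes, 6 for the urea cycle, 9 for amino acid breakdown, 8 for glutathione and 13 for plasma proteins. Camera did not call gluconeogenesis (median 0.02, adjusted p = 9.56e-01), glycolysis (0.06, adjusted p = 3.55e-01), fatty acid synthesis (0.025, adjusted p = 5.87e-01), cholesterol synthesis (0.06, adjusted p = 1.78e-01), acute phase proteins (−0.065, adjusted p = 2.15e-01) and Wnt targets (−0.10, adjusted p = 9.48e-02). In all, 22 of 39 lists passed camera, 10 upward and 12 downward, and 2 with an estimated correlation. Leaving out section 1 gave 883 genes and leaving out section 3 gave 943, against 1570 with all 4 sections, DESeq2 called 734, and edgeR without the section block 251.

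**Figure D5:**
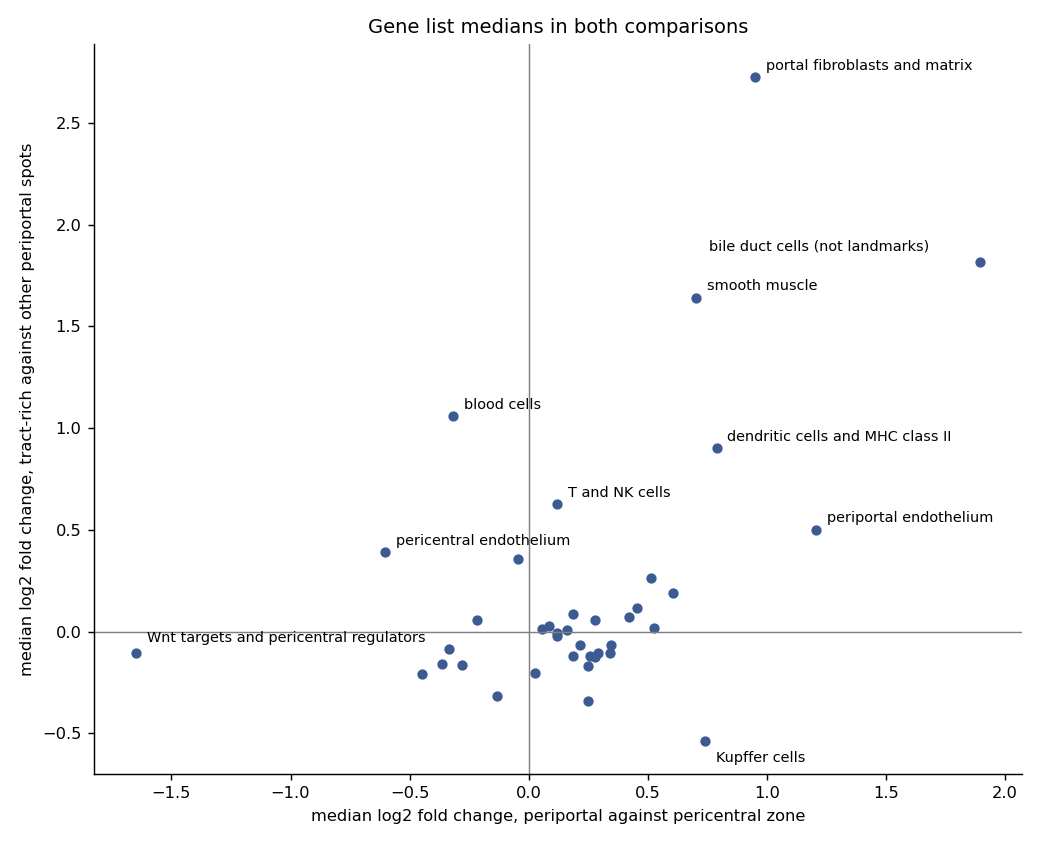
Median log2 fold change of each gene list between the periportal and pericentral zones (x axis) and between tract-rich and other periportal spots (y axis); each point is 1 list tested in both. Portal fibroblasts and matrix and bile duct genes lie at the upper right, and Kupffer cells alone reach below −0.5 on the y axis, at 0.74 and −0.54.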

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

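Of the tests in this part, the comparison of Marco with Kupffer cell genes of like level was chosen only after the result was seen. Among 82 sets of 4 section values, 7 had 1 section far from the other 3, where chance gives about 1 in 20, and several of these sets overlap in their UMIs. Section 2 stood apart in 5 of them. Its Marco log2 fold change between periportal and pericentral zones was 0.87, against 1.51 to 1.63 in the other sections, and its log2 ratio of Marco to other Kupffer cell genes was 0.44, against 0.86 to 0.92. Without section 2 the fitted fold change of Marco was 1.62 and the mean log2 ratio 0.89. C1qa was at 46.7 CPM in the periportal zone of section 2, against 60.8 to 61.6 elsewhere, and Cd5l at 45.1 CPM in its pericentral zone, against 35.0 to 36.3. Il10 was at 0.222 CPM in the periportal zone of section 2, against 0.0346 to 0.0484, from 5 UMIs against 1 in each other section. In section 4, Mup17 had a log2 fold change of −2.86, against −3.07 to −3.06, and Cib2 one of −2.27, against −3.08 to −3.01.

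Spots outside tissue held 17.7% of the UMIs of section 1, 11.6% of section 2, 6.70% of section 3 and 9.65% of section 4. Their profile correlated with that of the tissue at a Pearson r of 0.979 to 0.996 across 3430 to 3820 genes, which are not independent replicates. The median UMIs of spots 1 pitch from the tissue were 23.8%, 14.3%, 14.0% and 10.9% of the tissue median in sections 1 to 4, and 6.97%, 4.12%, 3.92% and 4.58% at 2 pitches.

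Marco differed more between the zones than any other of the 18 genes of the Kupffer cell list in each of the 4 sections, and 2 technical accounts were tested. Genes outside this list exceeded it, such as Il1rn in the fit (1.54 ± 0.21, SE) and in sections 2 to 4 (0.90, 1.76 and 2.12, against 0.87, 1.51 and 1.63 for Marco), and Msr1 (1.06 and 1.70) and Cd14 (0.89 and 1.72) in sections 2 and 4. Scatter of low counts would bring other genes of its level to like values, but of the 5 list genes at a comparable CPM the highest stood at 0.81 (Timd4), against 1.45 ± 0.11 (SE) for Marco. This SE is that of the fit, and Marco itself stood at 0.87 in section 2. An unequal loss of Kupffer cell genes near portal tracts would vanish without tract-rich spots, but the excess of Marco over the list median was then 0.72 ± 0.17 (SD, n = 4), against 0.69 with them. Spread of RNA between spots, which lowers all differences, stays open as a cause of their sizes. No biological explanation was tested, since all sections belonged to 1 group.

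Other splits of the region sums asked whether chance could give such counts. Sections pair the sums, and of 32 splits only 8, the real one included, part the regions of all 4 sections, too few for a share under 0.05. For the outer zones 1 of 32 splits, the real one, gave 4224 genes in a fit of these 8 sums, and the highest other gave 0 in edgeR (1301 against 5146 at an unadjusted p under 0.05). Maps of the position score rotated by a separate angle in each section gave at most 11 genes over 20 rotations against 4720. Maps as smooth as the score but out of place thus did not give the count for the outer zones. Rotation breaks any trend across a section that score and genes share, so such trends are not excluded. It also breaks the link to the landmark genes counted in the same spots, so it does not test what that link adds. The splits are too few to exclude chance. For tract-rich spots the real split gave 1570 genes and the highest other of the 32 gave 226 (1981 against 2777 at an unadjusted p under 0.05), and the other splits that part all sections gave 0 in edgeR (at most 696 at an unadjusted p under 0.05). For the middle zone the real labels gave 34 genes and the highest other of 60 labellings, the real one included, gave 0 genes in edgeR, but at an unadjusted p under 0.05 the highest other gave 1652 against 120, and 8 others gave more than the real labels. Other labels mix the larger difference between the outer zones into the contrast and its spread, a structure of the sums that keeps these splits from showing whether chance is excluded for the middle zone. A further 3 splits of each set of 8 sums could not be fitted.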

How the results depend on the processing

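A minimum of 10000 UMIs per spot, and thinning before the Marco ratio, were alternatives chosen after seeing the data. Periportal and pericentral zones differed in 4720 genes. That count was 4719 without a UMI minimum, 4445 in spots with 6 neighbours, 4656 by the Cyp2f2 to Cyp2e1 ratio, 4720 without this pair, 4028 by the first principal component, 4317 in outer zones of 20%, 4187 in 2 zones, 4689 with 10000 UMIs, 4715 with other size factors, 4994 unfiltered, 3369 in DESeq2 and 4115 to 4209 with 1 section left out. Thinned spots, with 8548 genes tested, gave 1600. For named genes in all comparisons, 2805 values under other settings kept their direction and side of the threshold, 183 kept the direction alone and 0 turned. Apart from those named whatever their result, these genes were chosen by their main result, which makes a turn unlikely.

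The middle zone had 34 genes, against 6 in thinned spots, 8 by the first principal component, 8 in DESeq2 and 12 to 24 with 1 section left out. Tract-rich spots had 1570 genes, against 189 in thinned spots with 5975 tested, 734 in DESeq2 and 883 to 1420 with 1 section left out. With an estimated correlation, lists past camera numbered 6 in place of 23 between outer zones, 0 in place of 18 in the middle (10 at an unadjusted p under 0.05, and 8 by fry) and 2 in place of 22 in tract-rich spots, where fry gave 10 and thinned spots 11. Apart from the genes tested in thinned spots, the cause was not tested.

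Without the replicate block, 1208 genes were called between outer zones, 251 for tract-rich spots and 0 by edgeR in the middle, where 10 passed at an unadjusted p under 0.05, and 11 lists passed in the middle. Of the named gene results 75 lost their call there, Marco included (1.44), as did 14 list results, and since the sections pair their own regions these losses are not weaker effects.

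The log2 Marco ratio of 0.78 was 0.61 with the sum of 4 other genes as denominator, 0.62 in 2 zones, 0.77 with 10000 UMIs, 1.15 in outer zones of 20%, 1.20 ± 0.87 (SD) in thinned spots, and 0.73 to 0.89 with 1 section left out. Periportal minus pericentral shares of spots, in percentage points, were 13.3 for Marco, 0.367 for Il10, 17.0 for Clec4f, 9.53 for Timd4 and 17.1 for Cd5l unthinned, as the number of UMIs sets a share. At 2000 UMIs they were 4.13 for Clec4f, 5.35 for Cd5l, 0.70 for Marco (above 0 in 3 of 4 sections) and 0.288 for Timd4 (in 2 of 4), against 1.77 for Marco and 1.35 for Timd4 at 5000.

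Camera turned its direction for lists it had not called between the outer zones. Their median log2 fold changes were then −0.24 in outer zones of 20% for B and plasma cells (0.055 to 0.88 with 1 section left out), and −0.009 to 0.053 with 1 section left out for sinusoidal endothelium. Stellate cells had 0.20 in spots with 6 neighbours, −0.019 thinned, 0.17 in outer zones of 20%, 0.044 unfiltered, 0.050 without the block and 0.014 to 0.24 with 1 section left out. Major urinary proteins had 0.10 thinned, −0.082 without the block and −0.14 to −0.036 with 1 section left out, and the cell cycle −0.18 to −0.008. Blood cells had −0.44 without the block and 0.95 by the first principal component, which camera then called upward (adjusted p = 9.80e-03, against up to 8.96e-01 under other settings). By that component the middle zone's upward calls turned for blood cells (−0.36) and cytochrome P450 (−0.028). Other list results kept direction and call in 1087 cases, lost the call in 65 and gained it in 13. The component followed the position score less closely in section 1, with a Spearman rho of 0.577 against 0.891 to 0.948 elsewhere across spots, and the cause of these turns was not tested.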

Other observations

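Of the tests in this part, those that set Kupffer cell genes against sinusoidal endothelium, and the use of tract-rich spots against macrophages of the tract itself, were chosen only after the result was seen. Tract-rich spots also held genes of lists that camera did not call. Of 11 genes of antimicrobial proteins and IgA transport 2 were higher and 5 lower, with Lcn2, an iron-withholding protein, at 13.5 ± 13.4 against 2.94 ± 1.93 CPM (SD, n = 4; log2 2.09 ± 0.16), Saa1 at 0.30 ± 0.05 and Hamp at −0.61 ± 0.04, and the list gave a camera adjusted p of 1.13e-01. Of 13 Notch, Hedgehog and Ras-side regulators 3 were higher and 2 lower, with the Notch ligand gene Jag1 at 1.55 ± 0.23, the Notch target Hes1 at 0.65 ± 0.11 and Igfbp2 at −0.47 ± 0.05 (adjusted p = 5.10e-01). Of 13 chemokine genes 2 were higher and 3 lower, Cx3cl1 standing at 2.23 ± 0.41 (adjusted p = 9.39e-01). Of 16 cholesterol synthesis genes 2 were higher and 1 lower, with Sqle, the squalene epoxidase gene, at 1.31 ± 0.17 (adjusted p = 1.78e-01), and the endothelin receptor gene Ednrb of the stellate cell list was at 1.13 ± 0.13. Of 18 acute phase genes 3 were higher and 7 lower, with the metallothionein gene Mt1 at −0.39 ± 0.05 (adjusted p = 2.15e-01). Each gene named so far moved the same way in 4 of 4 sections and passed edgeR's quasi-likelihood test. Thinning ended the calls of Saa1 (0.33) and Hes1 (0.71). Genes not past numbered 4, 8, 8, 13 and 8 in these 5 lists, and adjusted over the list alone the counts higher and lower were 2 and 6, 4 and 5, 3 and 3, 2 and 1, and 3 and 8, in the order given. In the middle zone, Cxcl13, which draws B cells, was highest (0.53 ± 0.13 and 0.70 ± 0.14 against the periportal and pericentral zones), in a chemokine list with 3 of 13 genes above the mean of the outer zones, 0 below and 10 not past (camera adjusted p = 7.21e-05, and adjusted p = 0.052 with an estimated correlation). The cyclin gene Ccnd1 was highest there too (0.71 ± 0.13 and 0.78 ± 0.13), alone among 15 cell cycle genes, with 0 below and 14 not past (adjusted p = 8.09e-02).

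Levels of several genes differed widely between the sections over all tissue spots. Rgs16 was at 0.617, 0.329, 70.7 and 22.8 CPM in sections 1 to 4, the metallothionein genes Mt1 at 72.1, 63.0, 1130 and 478 CPM and Mt2 at 4.52, 4.10, 131 and 41.3 CPM, and Lpin1, a regulator of lipid metabolism, at 27.7, 20.2, 321 and 158 CPM. Thrsp, a gene of fat synthesis, was at 74.3, 87.5, 390 and 113 CPM, and Mfsd2a at 7.51, 9.78, 77.7 and 30.9 CPM. Mup17 was at 2680, 4200, 572 and 1080 CPM, Cish at 38.3, 40.8, 5.07 and 14.0 CPM, and haemoglobin Hba-a1 at 1360, 526, 724 and 237 CPM. The Y-linked gene Ddx3y was at 15 to 22.2 CPM in the 4 sections, and Xist at 0.0165 CPM or less. Apart from this pair the genes were picked among the most different of the sections, so the values stand without a test.

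Genes of Kupffer cells were higher in the periportal zone, and 3 technical accounts were tested. A lower share of hepatocyte RNA would raise other sinusoidal cells alike, but the list median lay above that of sinusoidal endothelium by 0.72 ± 0.28 (SD, n = 4). For a gap in UMIs per spot, the median was 0.69 in thinned spots, against 0.74. Zones were set before thinning, which leaves the mix of genes in a spot unchanged on average. This test therefore could hardly have failed and does not decide that account. If macrophages of the tract itself made the rise, tract-rich spots should be highest, but the list median was −0.54 ± 0.13 there against other periportal spots. The rise of the list thus did not rest on tract-rich spots. Tract tissue in place of sinusoids could hide macrophages of the tract there, so what these add stays open. It also stays open whether cell number or RNA per cell differed, and no biological explanation was tested.

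Tract-rich spots had lower Kupffer cell genes, with 2 technical accounts tested. Tract tissue in place of sinusoids would lower sinusoidal endothelium alike, but the Kupffer list median lay below that of endothelium, at a difference of −0.39 ± 0.08 (SD, n = 4). Members of the endothelium list went both ways, with 7 of 16 lower and 2 higher. Clec4g (−0.47) and Oit3 (−0.48) fell nearly as far as the Kupffer list median, while Pecam1 rose (0.70). Endothelial genes of larger vessels may offset part of that fall, so the medians do not decide this account, which stays open. For a gap in UMIs per spot, the median was −0.65 in thinned spots, against −0.54. Classes of spots were set before thinning, so this test does not decide that account either. No biological explanation was tested.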
